A study of Homo sapiens with 12 samples.

How the data were processed

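RNA was measured in MDA-MB-453 cells, an established human breast cancer cell line that lacks estrogen receptor alpha. Per the labels' protocols, cells were grown for 72 h in high-glucose DMEM with 10% fetal bovine serum and treated for 6 h with 0.001% ethanol (vehicle) or 10 nM dihydrotestosterone (DHT), the most potent natural androgen. There were 6 libraries per group, described per the labels' protocols as independent replicates from consecutive passages of the line. Passages of a single line are not separate donors, so p-values measure the spread between these cultures. Libraries were made from 1 µg of RNA and read as single 40 bp reads on an Illumina instrument. The design text calls the assay poly-A RNA-seq while the protocol names a total RNA library kit, so the RNA class was not settled from the labels.

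The authors deposited a table of counts per gene, made with STAR and featureCounts on GRCh38 per the submitters' processing notes, with no versions or options given. Between 39.6% and 46.7% of the nonzero values in a library were not whole numbers (tolerance 0.005), so the values were taken as estimated counts, as deposited by the authors. Sharing of reads among placements or overlapping genes would give such values, and the options used are not given in the sources used here. The values were rounded to whole numbers before testing, although the test had been planned for raw counts. The counting of strand is not given in the sources used here. Paralogs, pseudogene copies, overlapping genes and antisense pairs are therefore uncertain, more so with 40 bp reads. A record of 1 gene was broken over 3 lines and was left out, which left 60670 genes, and 60400 identifiers matched the symbol table. Totals ran from 4345939 counts (vehicle replicate 6) to 25678380 counts (DHT replicate 2), so 1 count was worth 0.230 CPM in the shallowest library and 0.0389 CPM in the deepest. Floors and counting intervals cover counting error only.

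The authors also deposited a table of their own comparison with average log2 CPM, log2 fold changes, p-values and adjusted p-values for 14559 genes, per the file headers. The model behind it is not given in the sources used here. Its GC percent and transcript length columns, per the file headers, were used for the GC and length offsets and covered 89.0% of the genes tested here.

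Analysis was run in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 with group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05 over 16355 genes. Log2 fold changes are DHT over vehicle, and the standard error (SE) is the log2 fold change over the square root of F. CPM values are means ± SD of counts over TMM-scaled library totals. A gene with 0 counts in all vehicle libraries was compared with a floor of 3 counts over that group, and a gene with 1 to 3 vehicle counts is given as a ratio of pooled counts with an exact 95% binomial interval. Both were scaled by the TMM-scaled library totals summed over each group, so they differ from the ratio of the counts themselves.

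The named genes were chosen by a rule set before the data were examined, as were the lists and the alternatives not said to be added. The test was set then too, and was kept after its counts and those of other fits had been seen. The rule took the 12 largest rises and the 12 largest falls among genes with a symbol, adjusted p under 0.05, mean CPM of at least 1 and the same sign in all 6 replicate numbers. It added the 6 smallest p-values, up to 2 raised and 2 lowered members per list, and TFAP2B, FOXA1, GATA3, ERBB2, ERBB3, WNT7B and MYC. The rule gave 54 genes, with some items that are not reported here. Other genes in the text were chosen after their values were seen, and the text says so.

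Of 28 gene lists written from general knowledge, 25 had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. Beside this, the lists were tested with an estimated correlation per list and fry, a self-contained test of whether the genes of a list move one way on balance. An exact permutation test of list means over 924 labelings was added after seeing the data. Library measures were compared by exact two-sided permutation of the mean difference over 924 labelings, adjusted over 7 measures.

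The gene counts were recomputed with the replicate number as a block, DESeq2 1.42.0, limma-voom, other scalings, other filters, an adjusted p under 0.01, a test against a 1.2-fold change and each library left out in turn. Alternatives chosen after seeing the data left out both replicate 2 libraries, added GC and length offsets (splines with 5 degrees of freedom, with and without the block), tested against 1.1-fold and 1.3-fold changes, tested against 1.1-fold, 1.2-fold and 1.3-fold changes with the block, or kept the counts unrounded. The added tests against a fold were tried while looking for the model of the authors' deposited table.

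The fit was tested on simulated data for the DHT comparison with 200 changed genes among 16355. It recovered 14.9% of the genes changed 1.5-fold, 67.2% of those changed 2-fold and 100% of those changed 4-fold, with 4.72% false calls, and made 0 calls when no gene was changed. A list of 40 genes raised 1.3-fold passed camera at both correlations and fry, and 0 of 20 unchanged lists passed. Genes were drawn independently of each other there, the lists were random and no libraries were made to stand apart. The simulation therefore does not show how the list tests behave when genes of a list vary together. Same-group libraries were checked for duplicates: the lowest chi-square per gene among 30 pairs was 3.17, so no library was counted out.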

Results

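The data were 12 RNA-seq libraries of MDA-MB-453 cells, 6 treated with vehicle and 6 treated with 10 nM DHT for 6 h. The series title concerns the transcription factor AP-2β (TFAP2B) and enhancers of mammary hormone-sensing cells, and the comparison asked which genes androgen changed in a hormone-sensing tumour line. Vehicle libraries held 13187943 ± 4570227 counts (SD, n = 6) and DHT libraries 14774175 ± 5938684 counts (SD, n = 6), from 4345939 in vehicle replicate 6 to 25678380 in DHT replicate 2. A difference in depth between the groups did not pass (exact permutation p = 0.628, adjusted p = 0.929). Both replicate 2 libraries stood apart from the others on the first principal component, which held 51.1% of the variance, and DHT libraries lay above vehicle libraries on the second, with 15.7%. On the second, vehicle replicate 5 lay away from the other vehicle libraries, at -49.96, with vehicle replicate 6 next at -21.2.

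**Figure D1:**
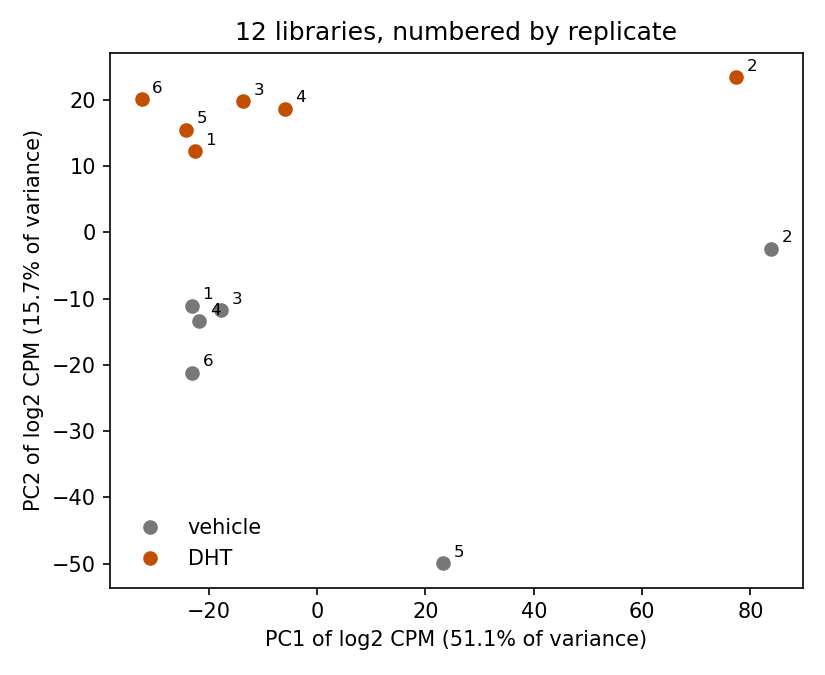
Principal components of log2 CPM for the 12 libraries, PC1 (51.1% of variance) across and PC2 (15.7%) up, with each point a library numbered by replicate. The replicate 2 libraries lie at 83.8 (vehicle) and 77.4 (DHT) on PC1, away from the rest, and vehicle replicate 5 lies lowest on PC2.

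DHT raised the lipid-binding protein gene SEC14L2 (ENSG00000100003, chromosome 22, 30396941 to 30425303 on GRCh38) from 8.05 ± 1.497 to 345 ± 48.7 CPM (log2 fold change 5.42, SE 0.17, adjusted p = 2.66e-10) and the water and glycerol channel gene AQP3 from 23.1 ± 4.46 to 384 ± 63.0 CPM (4.05, SE 0.17, adjusted p = 1.06e-08). The largest fall among genes that met the rule for size was that of PPP4R1L, a transcribed pseudogene, by 2.65 on the log2 scale (SE 0.30, adjusted p = 2.53e-04), followed by TP63, the transcription factor of basal epithelial cells, with a log2 fold change of -2.58 (SE 0.18, adjusted p = 2.41e-06). In all, 464 of 16355 genes changed, 320 raised and 144 lowered, and 150 of them changed at least 2-fold (102 raised, 48 lowered). Among the changed genes 402 were protein-coding and 18 were pseudogenes. At an unadjusted p under 0.05, 1961 genes passed. The count of changed genes moved by over 1.5 times when a single library was left out, to 306 without vehicle replicate 3 (208 raised), 278 without DHT replicate 1 (189 raised, 89 lowered), 282 without DHT replicate 3 (195 raised, 87 lowered), 301 without DHT replicate 4 (86 lowered) and 280 without DHT replicate 6 (194 raised, 86 lowered). DESeq2 called 778 genes, and leaving out both replicate 2 libraries gave 920, of which 457 were shared with the 464.

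Other genes named by the rule for size rose too. The tight junction gene CLDN8 rose from 5.85 ± 2.60 to 52.0 ± 11.2 CPM, C1orf116 from 3.14 ± 0.952 to 31.7 ± 5.87 CPM and RANBP3L from 2.03 ± 1.24 to 42.6 ± 13.1 CPM. MYBPC1, a myosin-binding protein gene, rose from 0.0799 ± 0.0925 to 4.82 ± 1.40 CPM, with 7 vehicle counts in all. Falls included AFP (alpha-fetoprotein) from 2.67 ± 1.06 to 0.445 ± 0.194 CPM, HABP2 from 5.03 ± 0.885 to 1.42 ± 0.466 CPM, FBN2 (fibrillin 2) from 8.10 ± 2.38 to 2.75 ± 1.12 CPM and the exchange factor gene DOCK2 from 13.96 ± 7.13 to 3.23 ± 1.96 CPM. KLHDC7A fell from 1.65 ± 0.617 to 0.411 ± 0.199 CPM, with 36 DHT counts in all (log2 fold change -2.01). The noncoding RNA gene LINC02233 also fell, with a log2 fold change of -2.49, and TPRG1 fell from 11.5 ± 3.54 to 2.89 ± 0.807 CPM. TDO2, which starts tryptophan breakdown to kynurenine, had a log2 fold change of -1.70 (adjusted p = 0.0194) that missed the threshold without DHT replicate 4 (adjusted p = 0.0528) or DHT replicate 6 (adjusted p = 0.0582). LINC02015 fell from 1.64 ± 0.297 to 0.543 ± 0.341 CPM, with 49 DHT counts in all. Its fall of 1.57 on the log2 scale had an adjusted p of 0.0507 without vehicle replicate 3. Of the 54 named genes, most of them selected for a large or consistent change, 28 lay higher in every DHT library than in any vehicle library, 18 lay lower and 8 overlapped.

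**Figure D2:**
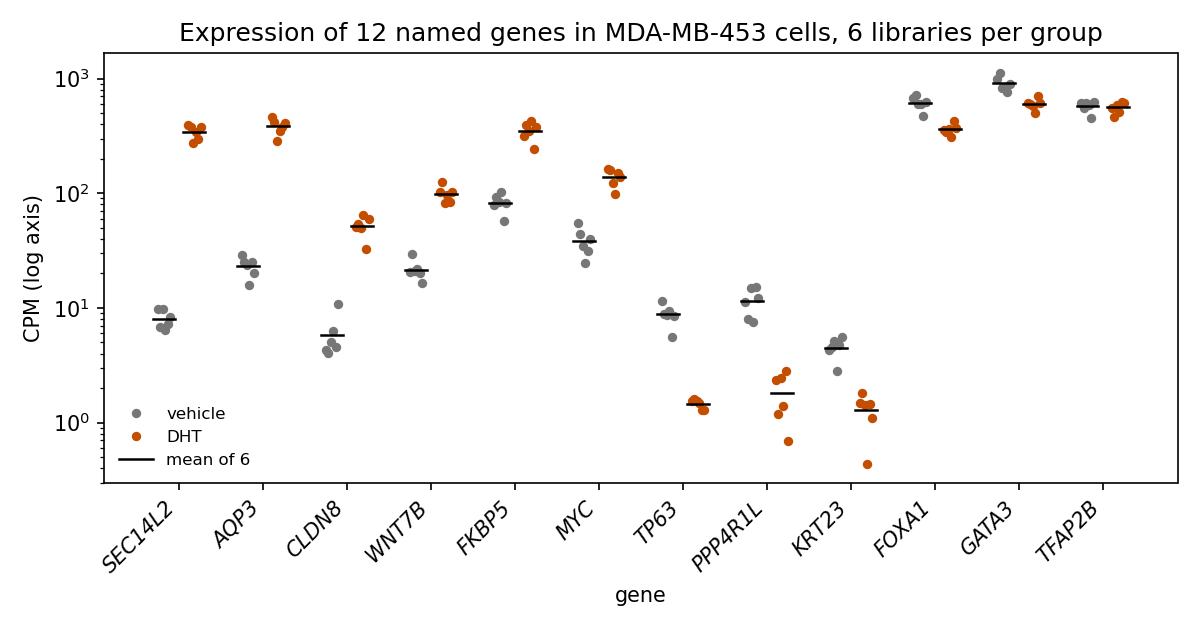
CPM on a log axis for 12 named genes, each point a library (6 vehicle in grey, 6 DHT in orange) and each bar the group mean. SEC14L2 and AQP3 lie higher in every DHT library, TP63 and FOXA1 lower, and the TFAP2B groups overlap (575 and 559 CPM).

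Genes of steroid inactivation and metabolism passed upward as a list, with a median log2 fold change of 0.19 (4 of 19 tested raised, 1 lowered, 14 not passing; adjusted over the list alone, 5 raised and 1 lowered; camera adjusted p = 3.07e-12, adjusted p = 0.00895 with an estimated correlation). The raised members were UGT2B10, UGT2B11 and UGT2B28, of a family that attaches glucuronic acid to steroids, and HSD11B2, which inactivates cortisol (UGT2B10 and HSD11B2 are named after their values were seen). UGT2B11 (chromosome 4, 69199951 to 69214748 on GRCh38) rose from 0.181 ± 0.140 to 18.1 ± 4.56 CPM (log2 fold change 6.85, SE 0.37, adjusted p = 1.42e-07). UGT2B28, on chromosome 4 from 69280475, had 3 counts over the vehicle libraries and 764 over the DHT libraries, a ratio of 220 after scaling for library totals (95% counting interval 74.97 to 1069). The pseudogene UGT2B25P had 2 and 237 counts, a scaled ratio of 102 (28.0 to 850), and UGT2B24P had 0 and 226 counts, at least 65.1-fold higher, scaled in the same way, over the floor of 3 counts for the group. These neighbours are near-identical and can share reads, so how the rise divides among them is uncertain. Camera counted UGT2B10, UGT2B11 and UGT2B28 as separate members, and the list was not tested without them. The lowered member was STS, steroid sulfatase, from 238 ± 48.1 to 130 ± 21.4 CPM (log2 fold change -0.88, SE 0.15, adjusted p = 0.00526).

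The apocrine secretory list held the same 3 UGT2B genes, AZGP1 and CYP4F8 among its raised members, AZGP1 being named after its values were seen (5 of 16 raised, 0 lowered, 11 not passing; 7 raised and 1 lowered adjusted over the list alone; camera adjusted p = 7.98e-19, adjusted p = 0.0424 with an estimated correlation). In edgeR 1 member was lower at an unadjusted p under 0.05, and DESeq2 and limma-voom each gave 0 lowered. The median log2 fold change of the list was 0.18. Because its raised UGT2B genes are also in the steroid list, the passing of these lists is not independent. CYP4F8, a cytochrome P450 of fatty acid and prostaglandin hydroxylation, rose from 0.409 ± 0.295 to 47.7 ± 21.2 CPM (log2 fold change 6.84, SE 0.55, adjusted p = 7.68e-06), and its paralogs can share reads too.

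Androgen target genes rose as a list (9 of 78 raised, 1 lowered, 68 not passing; 16 raised and 1 lowered adjusted over the list alone; camera adjusted p = 2.27e-07, adjusted p = 0.00931 with an estimated correlation). FKBP5, a chaperone partner of steroid receptors, rose from 82.4 ± 15.2 to 350 ± 63.9 CPM (log2 fold change 2.09, SE 0.16, adjusted p = 6.79e-06) and IQGAP2 from 25.8 ± 7.91 to 73.6 ± 14.1 CPM (1.51, SE 0.20, adjusted p = 6.35e-04). The lowered member, MAF, had a log2 fold change of -1.13 (adjusted p = 0.0220). It missed the threshold without any of vehicle replicates 1, 4 or 6 or DHT replicates 1, 3, 4 or 6, with adjusted p between 0.0509 and 0.0663. In the list of genes shared by androgens and glucocorticoids, 9 of 21 rose, 0 fell and 12 did not pass (11 raised and 0 lowered adjusted over the list alone; camera adjusted p = 1.44e-22, adjusted p = 0.00246 with an estimated correlation). Its members included ZBTB16, a zinc-finger repressor, which rose from 0.0702 ± 0.0910 to 2.96 ± 1.36 CPM (log2 fold change 5.57, SE 0.59, adjusted p = 1.03e-04), with 4 vehicle counts in all. For 0 lowered members here, edgeR at an unadjusted p under 0.05, DESeq2 and limma-voom each also gave 0.

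Genes of ribosome biogenesis and MYC targets rose together. Of 49 members 17 rose, 0 fell and 32 did not pass, and 31 rose adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 9.27e-33, adjusted p = 0.00246 with an estimated correlation). MYC, the growth-promoting transcription factor, rose from 38.4 ± 10.7 to 138 ± 24.3 CPM (log2 fold change 1.85, SE 0.19, adjusted p = 8.42e-05), and DKC1, the pseudouridine synthase of small nucleolar particles, from 363 ± 34.8 to 645 ± 52.7 CPM (0.83, SE 0.11, adjusted p = 8.11e-04). The number of raised members was 31 with GC and length offsets and 25 without both replicate 2 libraries. It fell to 11 without vehicle replicate 1, vehicle replicate 3, DHT replicate 3 or DHT replicate 6 and to 10 without DHT replicate 1. At an unadjusted p under 0.05, 33 rose and 0 fell, and DESeq2 and limma-voom also gave 0 lowered.

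The pioneer factor gene FOXA1 fell from 612 ± 83.6 to 363 ± 39.7 CPM (log2 fold change -0.75, SE 0.13, adjusted p = 0.00463). GATA3 went from 908 ± 132 to 601 ± 67.0 CPM (-0.59, SE 0.13, adjusted p = 0.0253), and its adjusted p was between 0.0531 and 0.0771 without any of vehicle replicates 1 or 6 or DHT replicates 1, 3, 4 or 6. TFAP2B, encoding AP-2β, stood at 575 ± 63.1 CPM in vehicle and 559 ± 61.5 CPM in DHT libraries (log2 fold change -0.04, SE 0.12, adjusted p = 0.961) and did not pass in any fit run. GRHL2, an epithelial transcription factor, rose from 124 ± 16.8 to 186 ± 15.96 CPM (0.58, SE 0.11, adjusted p = 0.0132). In the list of AP-2 and pioneer factors 1 of 14 rose, 2 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.169). Of the hormone-sensing luminal genes 3 of 31 rose, 3 fell and 25 did not pass (4 and 4 adjusted over the list alone, camera adjusted p = 0.103). At an unadjusted p under 0.05, 5 were higher and 8 lower. The count raised past the adjusted threshold fell to 1 without vehicle replicate 1, vehicle replicate 3 or DHT replicate 6. AFF3 rose from 3.25 ± 0.515 to 10.0 ± 1.83 CPM (1.60, SE 0.17, adjusted p = 9.93e-05). Without vehicle replicate 5, which had the highest mitochondrial share, camera passed for both lists, downward, with adjusted p of 0.0127 for AP-2 and pioneer factors and 0.0304 for hormone-sensing genes.

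WNT7B, a secreted WNT ligand (chromosome 22, 45920366 to 45977162), rose from 21.6 ± 4.25 to 99.2 ± 15.99 CPM (log2 fold change 2.20, SE 0.15, adjusted p = 1.77e-06). In its list 4 of 25 rose, 0 fell and 21 did not pass (6 raised adjusted over the list alone). Camera gave the list an adjusted p of 1.97e-05, or 0.229 with an estimated correlation. Its adjusted p was 0.0102 with fry and 0.0232 in the exact permutation of list means. LEF1, a nuclear effector of WNT signalling, had a log2 fold change of 1.00 (adjusted p = 0.0270). It missed the threshold without vehicle replicate 1, 3 or 4 or DHT replicate 1, 3, 4, 5 or 6, with adjusted p between 0.0530 and 0.0793. The raised count of the list fell to 1 without vehicle replicate 1 or 4 or DHT replicate 1, 3, 4 or 6. It fell to 2 without vehicle replicate 3 or DHT replicate 2 or 5. At an unadjusted p under 0.05, 1 member was lower, and DESeq2 and limma-voom each gave 0 lowered.

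Among ERBB receptors, ligands and feedback regulators 1 of 20 rose, 1 fell and 18 did not pass (3 and 5 adjusted over the list alone; camera adjusted p = 0.765). The lowered count was 2 without vehicle replicate 2, vehicle replicate 5 or DHT replicate 2. It was 0 without DHT replicate 1, 3 or 6, and DESeq2 raised 2 and lowered 3. SPRED1, an inhibitor of RAS signalling, rose from 102 ± 18.9 to 197 ± 21.2 CPM (log2 fold change 0.95, SE 0.14, adjusted p = 0.00133). GRB7, an adaptor of receptor kinases, had a log2 fold change of -0.74 (adjusted p = 0.0265), with adjusted p between 0.0663 and 0.0756 without DHT replicate 1, 3, 5 or 6. ERBB2 stood at 1263 ± 446 CPM in vehicle and 724 ± 166 CPM in DHT libraries and did not pass (log2 fold change -0.80, SE 0.21, adjusted p = 0.0649). It was lower in the DHT library for all 6 replicate numbers. The authors' deposited table gives ERBB2 a log2 fold change of -0.60 (adjusted p = 0.00189 there), and with the replicate block ERBB2 passed, as given below. It passed without vehicle replicate 2, its highest library (log2 fold change -0.58, adjusted p = 0.0440), without DHT replicate 2 (-0.93, adjusted p = 0.0246) and in DESeq2 (-0.79, adjusted p = 0.0122), with adjusted p between 0.00154 and 0.167 over 23 alternatives with group as the only term, 7 of them past the threshold. ERBB3 did not pass (log2 fold change -0.20, SE 0.14, adjusted p = 0.729).

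Markers of basal myoepithelial cells were lower as a list, with 1 of 11 lowered, 0 raised and 10 not passing (5 lowered adjusted over the list alone; camera adjusted p = 5.35e-06, adjusted p = 0.0153 with an estimated correlation). The lowered count was 2 without vehicle replicate 1, vehicle replicate 2 or DHT replicate 2, and DESeq2 lowered 3. TP63 (chromosome 3, 189631389 to 189897276) fell from 8.79 ± 1.91 to 1.46 ± 0.137 CPM. Of 5 tested luminal progenitor and alveolar markers, KRT23, a keratin gene, fell from 4.495 ± 0.945 to 1.28 ± 0.475 CPM (log2 fold change -1.76, SE 0.26, adjusted p = 0.00199) and 4 did not pass (1 lowered and 0 raised adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.318 with an estimated correlation, and by camera 0.0926 without vehicle replicate 5 and 0.0502 without both replicate 2 libraries). For both lists 0 members were raised at an unadjusted p under 0.05, in DESeq2 or in limma-voom. The 7 tested fibroblast markers gave 0 calls in edgeR with group as the only term, 5 lower at an unadjusted p under 0.05, 2 lowered in DESeq2 and 0 in limma-voom (3 lowered adjusted over the list alone; camera adjusted p = 0.00316, adjusted p = 0.224 with an estimated correlation). Leukocyte and endothelial lists had 2 tested members each, with 0 calls by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05.

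Of fatty acid synthesis genes 3 of 27 rose and 0 fell, with 24 not passing (4 raised adjusted over the list alone; camera adjusted p = 0.00625, adjusted p = 0.318 with an estimated correlation). The raised count was 1 without vehicle replicate 3, DHT replicate 3 or DHT replicate 6. It was 5 without vehicle replicate 2. ACACA, which commits acetyl-CoA to fatty acid synthesis, rose from 125 ± 22.2 to 193 ± 11.5 CPM (log2 fold change 0.62, SE 0.12, adjusted p = 0.0126). ACSL4 had a log2 fold change of 1.22 (adjusted p = 0.0191) and missed the threshold without vehicle replicate 3, DHT replicate 3 or DHT replicate 6 (adjusted p between 0.0525 and 0.0566). Of cholesterol genes 2 of 29 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.126). There were 0 raised without vehicle replicate 4, DHT replicate 4 or DHT replicate 6. There was 1 raised without vehicle replicate 1, 3 or 6 or DHT replicate 1, 3 or 5. INSIG2, which holds back sterol synthesis, fell from 160 ± 26.1 to 99.4 ± 11.6 CPM (adjusted p = 0.0103). MYLIP (log2 fold change 0.57, adjusted p = 0.0197) missed the threshold without vehicle replicate 4 or DHT replicate 4 or 6, with adjusted p between 0.0547 and 0.0588. ODC1, the first enzyme of polyamine synthesis, rose from 80.0 ± 9.31 to 126 ± 10.8 CPM (adjusted p = 0.00375), as 1 of 20 polyamine and transport genes with 0 lowered (3 raised adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.318 with an estimated correlation). The raised count of that list was 3 without vehicle replicate 2 and 2 in DESeq2. For the lists of this paragraph with 0 lowered, DESeq2 and limma-voom also gave 0, and the unadjusted counts were 0 for fatty acid and 1 for polyamine genes.

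Of immediate early genes 4 of 28 rose and 0 fell (4 raised adjusted over the list alone; camera adjusted p = 0.0263, adjusted p = 0.664 with an estimated correlation), JUN among them, from 24.7 ± 3.25 to 44.6 ± 6.23 CPM (adjusted p = 0.00157). For that list 1 member was lower at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0 lowered. Its camera adjusted p was 0.0883 without vehicle replicate 5 and 0.0502 without both replicate 2 libraries. Of unfolded protein response genes 2 of 47 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.960), with a median of -0.011 and a mean of -0.022 against an upward test. CREB3L1, a transcription factor of the secretory pathway, fell from 17.2 ± 3.13 to 7.44 ± 1.36 CPM (adjusted p = 9.72e-04). PDIA5 (log2 fold change 0.52, adjusted p = 0.0222) missed the threshold without vehicle replicate 3 or 4 or DHT replicate 1 or 6 (adjusted p between 0.0558 and 0.0690). ERN1 (0.89, adjusted p = 0.0268) missed it without vehicle replicate 3, 4 or 6 or DHT replicate 1, 3, 5 or 6 (adjusted p between 0.0515 and 0.0720). Hypoxia and glycolysis genes had 0 raised and 1 lowered of 31 (1 and 1 adjusted over the list alone; camera adjusted p = 0.399), with a median of -0.0014 against an upward mean and test. The median was 0.30 without vehicle replicate 2 and -0.22 without DHT replicate 2. For 0 raised, edgeR gave 3 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0. The raised count was 2 without vehicle replicate 2 or with library totals only. It was 1 without DHT replicate 5, with median-ratio or upper-quartile factors and with a filter of 1 CPM in 6 libraries. The lowered gene, EGLN3 (log2 fold change -0.54, adjusted p = 0.0220), missed the threshold without DHT replicate 1, 3, 4 or 6 (adjusted p between 0.0511 and 0.0720). Estrogen receptor targets had 1 raised of 22, STC2, and 0 lowered (1 and 0 adjusted over the list alone; camera adjusted p = 0.862). STC2 (12.2 ± 6.16 to 26.2 ± 2.69 CPM, adjusted p = 0.0212) missed the threshold without vehicle replicate 1, 3 or 6 or DHT replicate 6, with adjusted p between 0.0512 and 0.0589. The raised count was 2 without vehicle replicate 2. For that list 2 members were lower at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0.

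Several lists had no member past the threshold with all 12 libraries and group as the only term in edgeR, DESeq2 or limma-voom. They were S phase genes (0 of 55, 1 higher at an unadjusted p under 0.05, camera adjusted p = 0.0667), G2 and M phase genes (0 of 54, 1 higher and 4 lower at an unadjusted p under 0.05, camera adjusted p = 6.23e-04, adjusted p = 0.591 with an estimated correlation) and interferon response genes (0 of 38, 1 lower unadjusted, camera adjusted p = 0.00316, adjusted p = 0.591 with an estimated correlation). Adjusted over the list alone, 0 members of these lists passed. In edgeR 1 G2 and M phase gene was lowered without vehicle replicate 2 and 2 without both replicate 2 libraries. With DHT replicate 5 left out 1 S phase gene was raised, as was 1 with GC and length offsets. S phase genes passed camera, downward, without vehicle replicate 5 (adjusted p = 0.0219) and without both replicate 2 libraries (adjusted p = 0.0203).

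Measures of RNA content were compared as well. Mitochondrially encoded genes took 4.88 ± 1.81% of counts in vehicle and 3.42 ± 0.354% in DHT libraries (exact permutation p = 0.0563, adjusted p = 0.197), with 8.07% in vehicle replicate 5. Of their 13 genes 0 passed in edgeR, DESeq2 or limma-voom, 11 were lower at an unadjusted p under 0.05 and 11 were lowered adjusted over the list alone (median log2 fold change -0.65, camera adjusted p = 5.35e-06, adjusted p = 0.318 with an estimated correlation). The median was -0.38 without vehicle replicate 5. Histone genes gave 0 of 30 by all of these tools and adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0310, adjusted p = 0.655 with an estimated correlation, and by camera 0.241 without vehicle replicate 5 and 0.0926 without both replicate 2 libraries). The list of non-polyadenylated RNA genes had 2 tested members, with 0 passing by any tool or at an unadjusted p under 0.05. The share of the 10 most abundant genes was 5.33 ± 1.497% in vehicle and 3.97 ± 0.214% in DHT libraries (exact permutation p = 0.0216, adjusted p = 0.152).

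In all, 16 of 25 lists passed camera at the preset correlation and 6 with an estimated correlation: ribosome biogenesis and MYC targets, the shared androgen and glucocorticoid list, steroid inactivation, androgen targets, apocrine secretory genes and basal markers. The steroid inactivation and apocrine secretory lists share their raised UGT2B genes.

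**Figure D3:**
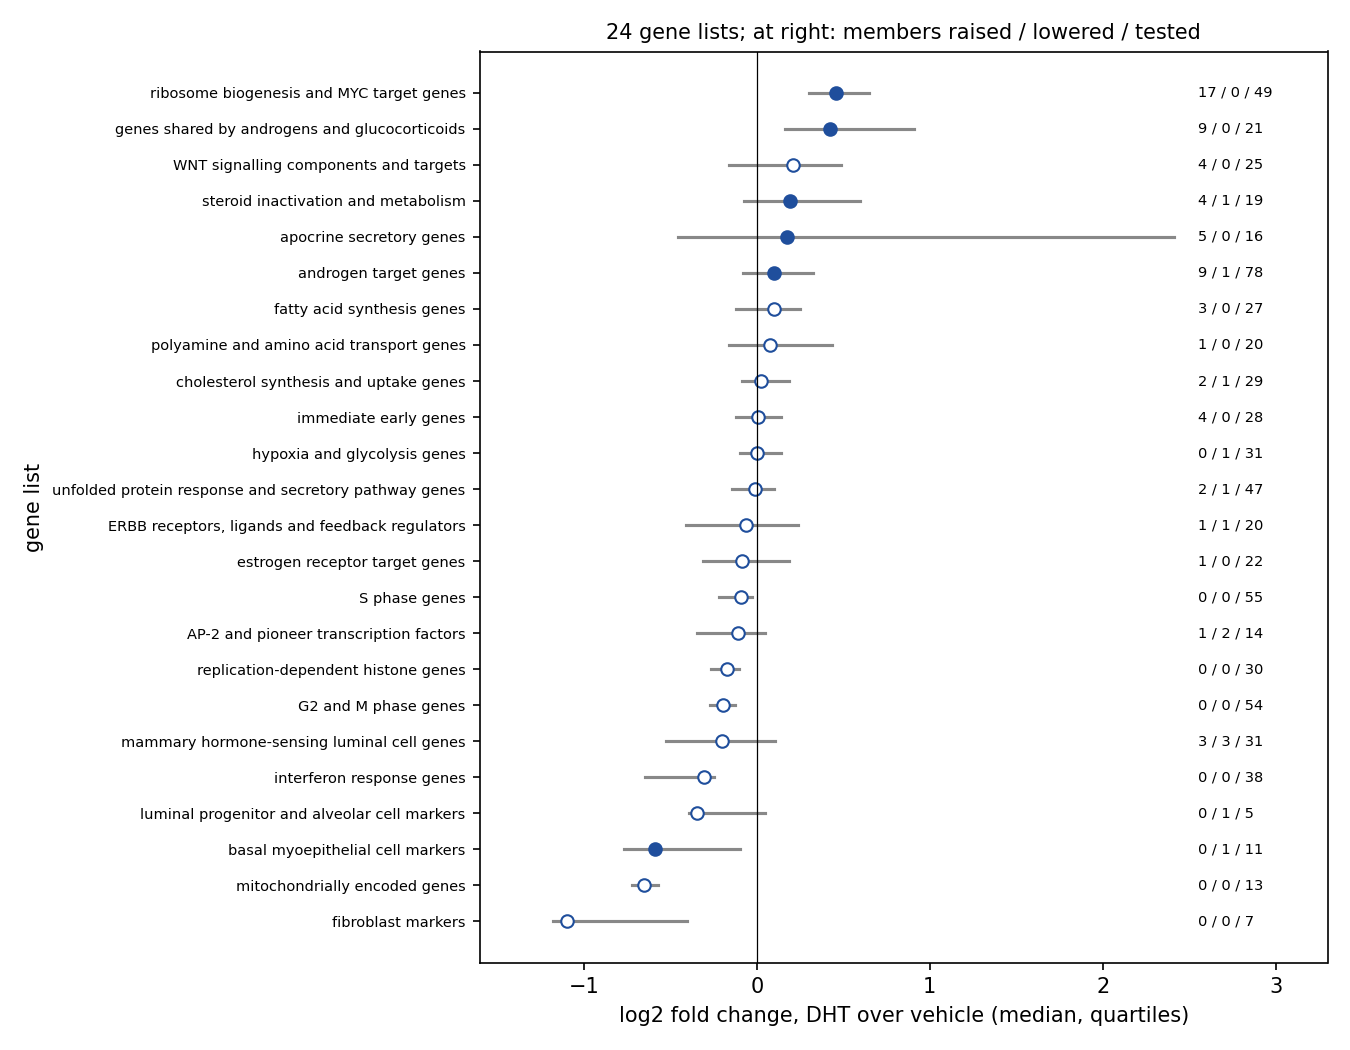
Log2 fold change of DHT over vehicle for 24 of the 25 gene lists, with the point at the median of tested members, the line spanning the quartiles, and the numbers raised, lowered and tested at the right. Filled points mark the 6 lists that passed with an estimated correlation; the highest median is 0.46, for ribosome biogenesis and MYC targets.

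The authors' deposited table lists 14559 genes, with 619 at an adjusted p under 0.05, of which 387 are positive and 232 negative in the authors' deposited table. All 619 had the same sign in the counts, and 375 of the 619 calls of the authors' deposited table were among the 464 genes changed here. Of the 464, 437 are listed in the authors' deposited table. GATA3 (adjusted p = 0.127 there), EGLN3 (0.137) and MYLIP (0.0516) changed here and are not called there, while ERBB2 is called only there. Log2 fold changes of the authors' deposited table and of the counts correlated across genes (Pearson r = 0.942), which are not independent replicates.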

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

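The tests of other splits, of GC content and length, of the stress response genes, of the ribosome biogenesis genes and of shared reads were written down after their results or the underlying values had been seen. Of 124 groups of 6 values looked at, 9 had an extreme library far from the others, where chance gives about 1 in 20, and 4 of the 9 were replicate 2 libraries. Each library was compared with the other 5 of its own group only. Among vehicle libraries, vehicle replicate 6 had the lowest total, 4345939 counts against 13240832 for the next, and the lowest share of values that were not whole, 39.6% against 43.8%. Among DHT libraries, DHT replicate 2 had the highest share of ribosomal protein genes, 4.36% against 2.93% for the next. In log2 CPM within its group, DHT replicate 2 was lowest for CYP4F8 at 3.01 (next 5.49), vehicle replicate 2 highest for STC2 at 4.63 (next 3.39) and for ERBB2 at 11.08 (next 10.16). Within their groups, vehicle replicate 3 was lowest for CREB3L1 at 3.48 (next 4.10), vehicle replicate 5 lowest for GRHL2 at 6.53 (next 6.95) and DHT replicate 5 highest for MAF at 2.08 (next 1.34).

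Of 100 of the 462 splits of the 12 libraries into 6 and 6, drawn with the real split included, 1 gave as many changed genes as the real split, namely the real one with 464, and the highest other count was 0. The same held for 320 raised, 144 lowered and 150 genes changed at least 2-fold, with 1 split as large and 0 in the highest other. That is a share of 1 in 100, the smallest that this draw can give, so chance is not excluded beyond that share. At an unadjusted p under 0.05 other splits reached 4252 genes against 1961, and that split had both replicate 2 libraries on the same side, which points to a structure of the libraries other than the treatment. For the lists, 2 of 100 splits gave as many as 16 passing lists, the real one included, a share of splits under 0.05. The highest other split also gave 16, and the median of the others was 7, so single lists that passed only at the preset correlation stay uncertain.

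Both replicate 2 libraries stood apart from the other 10, and a smooth on GC content and transcript length held 33.1% of the deviation of the vehicle library and 20.5% of that of the DHT library. Such shares were not particular to this pair, with 29.3% for vehicle replicate 5 and 26.4% for DHT replicate 6. After the smooth was taken out, 71.6% of the squared distance of the replicate 2 pair from the others remained, 6.04 times that of the farthest other same-numbered pair, which argues against GC content and length as the whole cause. A list of 31 integrated stress response genes, an idea taken from other genes high in these same libraries, lay above 100% of 10000 matched random lists in both libraries (median deviations 0.74 and 0.62), and so did the 27 left without 4 genes seen in earlier output. This is in line with a stress response of those cultures as a hypothesis, though genes of a pathway vary together and random lists do not. The labels give no difference for these cultures, so no biological explanation from the design was tested, and a separate handling or library batch stays open.

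Ribosome biogenesis and MYC target genes rose as a list. With GC and length offsets 31 of 49 members were raised (median log2 fold change 0.48), which argues against GC content and length as the whole cause. Without both replicate 2 libraries 25 were raised (median 0.45), which argues against those libraries as the whole cause. A response to DHT, the difference the design names, stays open as a hypothesis beside technical differences that were not tested.

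Pseudogene copies rose with their parent genes. AZGP1P1 (chosen after its values were seen) stood at 0.159 ± 0.00554 of AZGP1 counts in vehicle and 0.181 ± 0.00928 in DHT libraries (n = 6 each, exact two-sided permutation p = 0.00433), which argues against a fixed share of AZGP1 reads as the whole of its rise. A share of reads that shifts with the coverage along AZGP1 was not tested. For UGT2B24P, UGT2B25P and UGT2B27P the ratio to UGT2B11 and UGT2B28 counts lay between 0.220 and 0.265 in the DHT libraries and did not differ beyond counting noise (chi-square p = 0.852). Shared reads and transcripts of their own cannot be told apart there, because both allow a constant ratio and the vehicle libraries held too few counts for a comparison.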

How the results depend on the processing

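The alternatives that left out both replicate 2 libraries, added GC and length offsets, tested against a 1.1-fold or 1.3-fold change, combined the block with a fold, kept the counts unrounded or permuted list means were chosen after seeing the data. Of 1341 values of named genes under alternatives, 1237 kept their direction and side of the threshold, 93 lost it, 9 gained it and 2 reversed. The reversed values were those of TFAP2B, 0.012 with library totals only and 0.0062 without DHT replicate 2 (-0.099 to 0.0062 over the libraries left out). The number of genes changed at least 2-fold stayed within 1.5 times of 150 except in a test against a 1.3-fold change, with 92. With DESeq2, 778 genes changed, 514 raised and 264 lowered. With both replicate 2 libraries left out the counts were 920, 608 and 312, and with GC and length offsets 826, 538 and 288. An adjusted p under 0.01 left 195, 137 and 58, and a test against a 1.2-fold change left 201, 137 and 64, and against a 1.3-fold change 120, 85 and 35, as stricter thresholds must. Library totals only gave 93 lowered, with the median log2 fold change 0.058 higher than in the main fit. No expression filter gave 90 lowered, with 35561 genes tested instead of 16355. Whether these differences account for the whole drop was not tested. Leaving out 1 library gave 278 to 619 changed, 189 to 434 raised and 86 to 199 lowered. The number of raised or lowered members moved by over 1.5 times when 1 library was left out for 16 of 25 lists. Lists that passed numbered 6 with an estimated correlation, 8 with fry and 7 in the exact permutation of list means, against 16. The WNT list was among the 8 and the 7, and the luminal progenitor list among the 8. The lists of estrogen receptor targets (adjusted p = 0.434 without both replicate 2 libraries) and of unfolded protein response genes (adjusted p = 0.943 with fry, 0.997 with GC and length offsets) changed direction without passing in any fit.

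The labels do not tie a vehicle library to the DHT library of the same number, and the libraries were taken to share only a number. Deviations from group means correlated over 0.1 in 5 of 6 same-numbered pairs, with 0.87 for replicate 2 and -0.24 for replicate 5. The mean correlation was 0.384 for same-numbered pairs and -0.019 for other pairs of a vehicle and a DHT library. Of 12 libraries, 6 correlated best with their own number, so a shared passage stays possible. Counts of both fits had been seen when this was settled. With the replicate block the counts rose to 1286 changed, 764 raised and 522 lowered (59.4% raised against 69.0%), all 464 genes were called with the same sign, and 19 lists passed. With it 6 interferon response genes and 2 G2 and M phase genes were lowered, and 1 S phase gene was raised and 1 lowered. The block also lowered 5 fibroblast markers, 3 histone genes, 3 estrogen receptor targets and 2 apocrine secretory genes. It lowered 1 gene in each of the WNT, immediate early and polyamine lists. Of hypoxia and glycolysis genes 6 were raised and 1 lowered with the block. Of hormone-sensing luminal genes 5 were raised and 10 lowered with it, and camera passed downward (adjusted p = 0.0437). ERBB2, which did not pass without the block, passed with it (log2 fold change -0.77, adjusted p = 0.00108), and 608 of the 619 calls of the authors' deposited table were called with the block, against 375 without it. Block and fold together gave 849, 547 and 302 against a 1.1-fold change and 270, 189 and 81 against a 1.3-fold change. With GC and length offsets and the block the counts were 2283, 1284 and 999, of which 56.2% were raised. In the shallowest library 1 count was worth 0.230 CPM, which limits what the counts show of genes near that level. In simulation 14.9% of genes changed 1.5-fold were recovered, and depth was not varied there.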

Other observations

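The genes of this part were chosen after their values were seen, while the tests of neighbours were written down before their counts were seen, the test of distant pairs after the count of all pairs. Of the 6 tested Iroquois homeobox genes 5 rose in edgeR, and all 6 had positive log2 fold changes under each of the 4 scalings. IRX3 rose from 122 to 269 CPM (log2 fold change 1.14, SE 0.13, adjusted p = 2.90e-04), IRX5 from 136 to 197 CPM (0.54, adjusted p = 0.00410) and IRX6 from 0.830 to 1.92 CPM (1.17, adjusted p = 0.0180), and these calls held with each library left out. IRX1 (0.91, adjusted p = 0.0227) missed the threshold without vehicle replicate 1, 3, 4 or 6 or DHT replicate 1, 3 or 6, with adjusted p between 0.0501 and 0.0652. IRX4 (0.51, adjusted p = 0.0433) missed it with library totals (adjusted p = 0.0749) and without vehicle replicate 1, 3, 4 or 6 or any 1 DHT library, with adjusted p between 0.0557 and 0.111. IRX2 did not pass (0.27, adjusted p = 0.563).

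Among enzymes of the kynurenine pathway KMO fell from 77.4 to 26.5 CPM (log2 fold change -1.55, SE 0.16, adjusted p = 9.93e-05), beside TDO2, and KYNU stood at 1.09 and 0.690 CPM (adjusted p = 0.506). The phospholipid enzyme genes CHPT1 and PISD rose, CHPT1 from 39.95 to 123 CPM and PISD from 46.1 to 96.1 CPM, as did DDC, which makes dopamine and serotonin, from 1.92 to 5.66 CPM. MYCN went the other way to MYC, from 4.55 to 1.60 CPM (log2 fold change -1.49, SE 0.28, adjusted p = 0.00868). The chemokine receptor gene CXCR4 fell from 24.4 to 8.71 CPM (adjusted p = 0.00767).

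TP63 and TPRG1, consecutive tested genes on chromosome 3, both fell, and the hypothesis was tested that changed genes lie next to each other. Among consecutive tested genes that neither overlap nor have like names, 16 pairs were both raised, against a mean of 4.83 in 10000 permutations within expression deciles (one-sided permutation p = 0.0001, the smallest they can give), MYBPC1 with CHPT1 among them. For lowered genes there were 5 pairs against 0.970 (one-sided permutation p = 0.0034), the TP63 pair that gave the idea among them. Without TP63 and TPRG1, a test added after that result, there were 4 pairs against 0.922 (one-sided permutation p = 0.014), TDO2 with CTSO among them. Raised pairs at least 10 kb apart numbered 13 against 3.23 (one-sided permutation p = 0.0001, again the smallest), which argues against read-through over shorter distances as the whole cause. Regulatory elements shared by neighbours may account for these pairs, and longer read-through, pseudogenes among the pairs and other chromosome-scale differences were not tested.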
